A study of Homo sapiens with 4 samples.

How the data were processed

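Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map CDK8 in HCT116 cells, an established human colorectal cancer line. CDK8 is a kinase of the Mediator complex, which links transcription factors to RNA polymerase II. The series holds 4 samples: 1 CDK8 library from normoxic cells, 2 CDK8 libraries from cells kept in hypoxia (1% oxygen for 24 h), labelled replicates 1 and 2, and 1 input library. Per the labels' protocols, chromatin was cross-linked with formaldehyde, sonicated and precipitated with an antibody against CDK8. The labels do not say whether the 2 hypoxia libraries came from separate cultures, so the spread between them may be technical. The input library was not analysed here.

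The deposited files are 3 peak lists, 1 per CDK8 library. Their names mark them as merged without saying what was merged, so a list may combine several sequencing runs or precipitations. Each line gives a chromosome, a start and an end in bp, a peak name of the kind MACS writes, and a score. Per the submitters' processing notes, the tools were CASAVA 1.8.2, FastQC, Bowtie 0.12.7 and MACS2 2.0.9, and the genome build was GRCh37/hg19; the notes as used here give no role, order or parameter for them. Per the series design text, CDK8 was compared with input. Read filters, duplicate removal and the calling threshold are not given in the sources used here. The score in the deposited lists is the authors' own value for each peak, and its scale is not stated. The lowest score was 5.00 in normoxia, 5.01 in hypoxia replicate 1 and 5.05 in hypoxia replicate 2. The score was used to rank or filter peaks within a list, as a percentile in which 100 is the best peak of that list, and was never compared between lists as an amount of binding. A peak that 1 list holds and another lacks may have fallen just under the threshold in the second, so presence and absence depend on depth. Read depth is unknown, since the lists hold no read counts.

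The starts in the lists count from 0; coordinates are given here counted from 1. Overlap between libraries was computed with bedtools 2.31.1 and required at least 1 bp. The overlap index of a pair of lists is the number of peaks of both lists that overlap the other list, as a percent of all peaks of both lists. Shares have Wilson 95% intervals, which cover counting error only and not the differences between cultures, precipitations or libraries. In the overlap index a shared site is counted from each list as if independent, so its intervals are too narrow even for counting error. For a count of 0 the upper limit is the share that 3 counts would give. Chance overlap was taken from 100 random placements of the second list, each peak keeping its chromosome and width. The lengths of the chromosomes were not given, so placements and peaks per Mb used the span from the first to the last listed peak of a chromosome over the 3 lists. For presence patterns, touching or overlapping peaks of the 3 lists were joined into regions, and each region was assigned to 1 of 7 patterns by the lists that hold a peak in it. Spearman's rho of percentile ranks was computed across regions, which are not independent replicates; its interval over regions in all 3 lists comes from 1000 bootstrap resamples of regions. The joining, the pattern counts and the overlap index were tested on simulated lists holding 21900 regions over the 7 patterns. The largest deviation of a recovered count was 0%. The simulated regions lay far apart and held at most 1 peak per list, so this was a check of the code alone. It did not cover regions that lie close together or hold several peaks of a list. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

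No test between conditions was run and no p-value is given: with 1 normoxia and 2 hypoxia libraries, an exact permutation of the labels could not give a p below 0.333. The difference between the 2 hypoxia libraries serves as the only available error against which normoxia is set, and it rests on a single pair. The comparisons, the processing alternatives and the rule for naming regions were fixed before the data were examined. The rule takes 10 regions from each of 3 classes: regions in both hypoxia libraries and not in normoxia, ranked by the lower of their 2 percentiles, regions in normoxia alone, ranked by its percentile, and regions in all 3 libraries, ranked by the lowest of their 3 percentiles. Alternatives were the better-scoring 50% of each list, equal list sizes (the 14256 best peaks of each list), chromosomes 1 to 22 and X alone, an overlap of 50% of both peaks, peak centres within 500 bp, joining of peaks within 500 bp, and leaving out either hypoxia library. Leaving out chromosome Y and windows rich in peaks of hypoxia replicate 1 was added after seeing the data, as were the distances between regions and the clusters of regions.

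No annotation or sequence of GRCh37/hg19 enters any value given here. Gene models, chromosome bands and CpG islands of that build, from installed software packages, had been set against the peaks in a first exploration and were then left out, because they did not come with the series. That exploration had shown many peaks of hypoxia replicate 1 in centromeric and variable bands before the 1 Mb windows were defined from the peak lists, so the windows were not chosen independently of an annotation. The table of gene names at hand belongs to GRCh38.p14, whose coordinates cannot be set against these peaks. The planned counts of peaks by genomic class, of genes with a peak at their start, of members of fixed gene lists and of sequence motifs were therefore not run. Regions are named by chromosome, start and end, and whether they lie in a gene, exon or intron is not stated.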

Results

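CDK8 was mapped by ChIP-seq in HCT116 colorectal cancer cells under normoxia (1 library) and after 24 h in 1% oxygen (2 libraries). The normoxia list held 19862 peaks covering 9.20 Mb, with a median width of 379 bp. Hypoxia replicate 1 held 21993 peaks covering 8.12 Mb, with a median width of 295 bp. Hypoxia replicate 2 held 14256 peaks covering 5.97 Mb, with a median width of 352 bp. The normoxia count lay between those of the 2 hypoxia libraries, so a difference in the number of CDK8 peaks between the conditions was not larger than the difference between the hypoxia libraries. Read depth is unknown, and peak numbers depend on it. There is no replicate of normoxia, and values below have no error between normoxic cultures.

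The first question was where CDK8 was found under both conditions, taken strictly as regions listed in all 3 libraries. A further 4463 regions were in normoxia and hypoxia replicate 1 only, and 1872 in normoxia and hypoxia replicate 2 only. The strict count is therefore a lower bound on what the conditions shared. Joining the 3 lists gave 28150 regions, of which 9295 (33.0%, 95% interval 32.5 to 33.6) were listed in all 3 libraries. Their median width of 559 bp was the highest of the 7 patterns, against 277 bp for regions of normoxia alone, 231 bp for hypoxia replicate 1 alone and 265 bp for hypoxia replicate 2 alone; joining overlapping peaks of several lists widens a region, which sets part of this order. Of 227 regions wider than 2 kb, 199 were in all 3 libraries. The region that ranked first by the lowest of its 3 percentiles was 893 bp on chromosome 19 (597259 to 598151), the best-scoring peak of the normoxia list and of the hypoxia replicate 2 list. Next came 1091 bp on chromosome 1 (228674245 to 228675335) and 3746 bp on chromosome 6 (30709024 to 30712769). A region on chromosome 7 (90893462 to 90894069) held the best-scoring peak of hypoxia replicate 1, and ranked at percentile 99.9 in each of the other lists. The 10 top regions also included a pair on chromosome 17 (61919795 to 61920795 and 79367432 to 79368140), another on chromosome 19 (3721257 to 3721944) and one on chromosome 5 (81046968 to 81047834). A pair of broad ones lay on chromosome 20 (30191689 to 30197528, 5840 bp) and chromosome 8 (126441283 to 126446557, 5275 bp). The lowest percentile of any of the 10 in any library was 99.86. The widest region in all 3 libraries spanned 8491 bp on chromosome 17 (57914136 to 57922626). It was listed as 1 peak in normoxia and as 2 in each hypoxia library, at percentiles of 99.7, 99.95 and 99.8 in normoxia, hypoxia replicate 1 and hypoxia replicate 2.

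**Figure D1:**
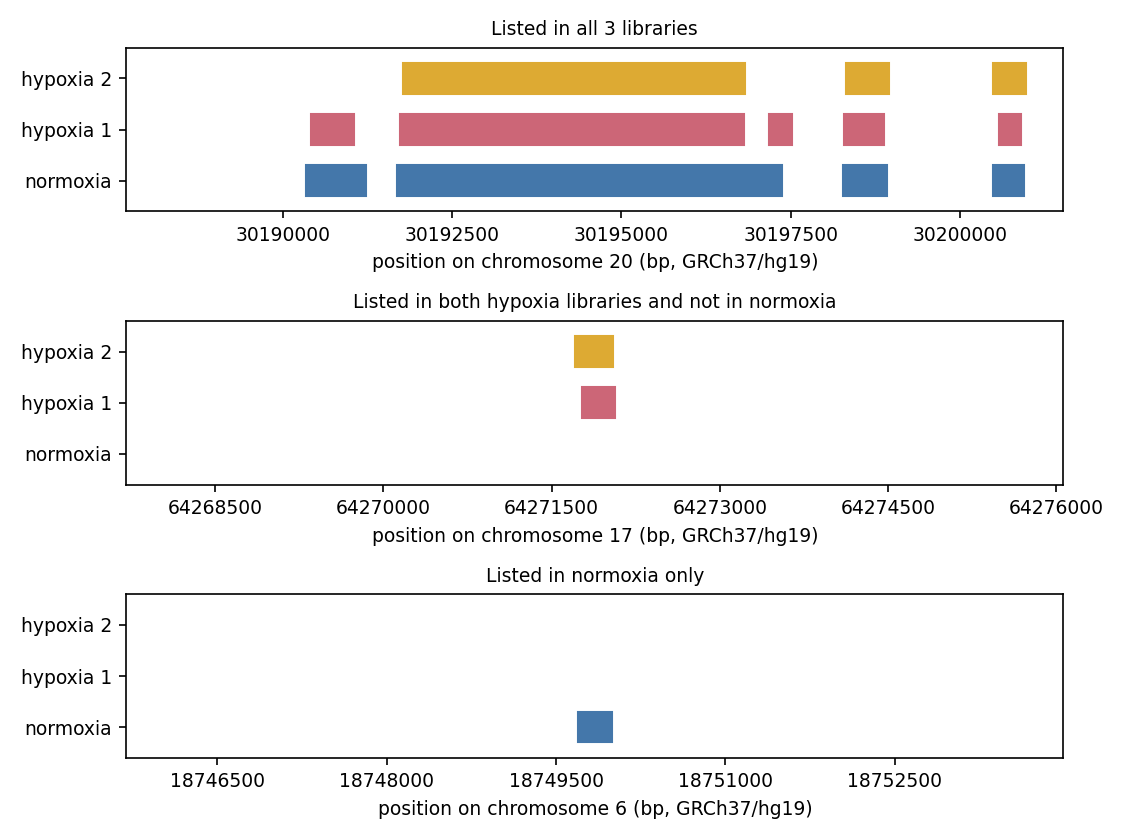
Listed CDK8 peaks in 3 named regions, drawn as boxes against position in bp on GRCh37/hg19, with 1 row per library and 4 kb on either side of the region. The region on chromosome 20 is covered in all 3 libraries, the one on chromosome 17 (64271709 to 64272063) in both hypoxia libraries, and the one on chromosome 6 (18749695 to 18749992) in normoxia.

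High-scoring peaks were shared far more often than low-scoring ones. In the top quintile of scores, 88.8% (87.8 to 89.7) of normoxia peaks overlapped a peak in both hypoxia lists. The corresponding share was 80.4% (79.2 to 81.5) for hypoxia replicate 1 and 93.0% (92.0 to 93.9) for hypoxia replicate 2. In the bottom quintile the shares were 17.1% (16.0 to 18.3), 19.0% (17.9 to 20.2) and 45.5% (43.7 to 47.3). Hypoxia replicate 2 has the shortest list and its peaks were sought in both longer ones, which favours its shares. The shares were not computed with equal list sizes, so they do not rank the libraries by reproducibility. Of the top-quintile normoxia peaks, 0.780% were in neither hypoxia list. Of the top-quintile peaks of hypoxia replicate 1, 6.73% were in neither other list, and of those of hypoxia replicate 2, 0.737%. Requiring an overlap of 50% of both peaks lowered the top-quintile shares to 66.4%, 64.9% and 72.4%.

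**Figure D2:**
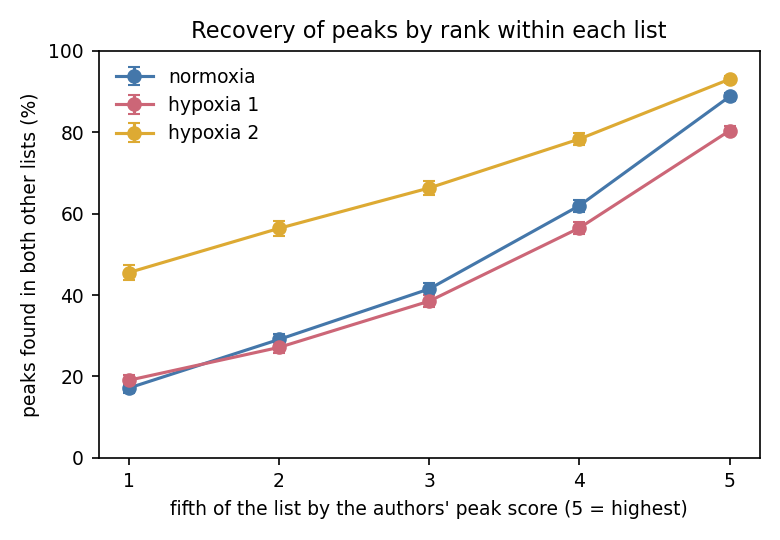
Share of peaks found in both other lists (percent, with 95% Wilson intervals as bars) by quintile of the authors' score within each list, from 1 (lowest) to 5 (highest). The share rises in each library, from 17.1% to 88.8% in normoxia.

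The series sets hypoxia against normoxia, and the overlap of the 2 hypoxia libraries is the only available measure of error for that comparison. The 2 hypoxia libraries overlapped least. Hypoxia replicate 1 found 74.5% (73.8 to 75.2) of the peaks of hypoxia replicate 2, and hypoxia replicate 2 found 48.8% (48.1 to 49.4) of those of hypoxia replicate 1, an overlap index of 58.9% (58.4 to 59.4). The index was 68.8% (68.4 to 69.3) between normoxia and hypoxia replicate 1 and 68.1% (67.6 to 68.6) between normoxia and hypoxia replicate 2. Random placements gave mean indices of 0.561%, 0.710% and 0.628% for these 3 pairs. By shared length the order was alike, with Jaccard indices of 0.360 between the hypoxia libraries, 0.444 between normoxia and hypoxia replicate 1 and 0.441 between normoxia and hypoxia replicate 2. Across the regions shared by a pair of lists, Spearman's rho of percentile ranks was 0.489 for the hypoxia libraries (10189 regions), 0.612 for normoxia and hypoxia replicate 1 (13758 regions) and 0.605 for normoxia and hypoxia replicate 2 (11167 regions). By these measures normoxia differed from either hypoxia library by less than the hypoxia libraries differed from each other. The hypoxia pair may hold a technical difference: the shortest listed peak was 181 bp in hypoxia replicate 1 and 225 bp in hypoxia replicate 2. Normoxia, at 226 bp, also differed in this from hypoxia replicate 1. A single such pair cannot show how any effect of hypoxia compares with the usual spread between replicates.

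Regions gained under hypoxia were sought as those in both hypoxia libraries and not in normoxia. There were 894 (3.18% of all regions, 2.98 to 3.39), the smallest of the 7 patterns. The 2 other patterns that lack a single library were larger, with 4463 regions in normoxia and hypoxia replicate 1 and 1872 in normoxia and hypoxia replicate 2. Normoxia therefore listed 91.2% (90.7 to 91.8) of the 10189 regions that the 2 hypoxia libraries shared. By the same count, hypoxia replicate 1 listed 83.2% (82.5 to 83.9) and hypoxia replicate 2 listed 67.6% (66.8 to 68.3) of the regions shared by the other pair. With equal list sizes the 3 patterns held 1129, 2151 and 2438 regions, and the pattern of both hypoxia libraries was again the smallest of the 7. The count rests on having both hypoxia libraries: normoxia lacked 7352 regions of hypoxia replicate 1 taken alone and 2478 of hypoxia replicate 2 taken alone.

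The 894 regions had a median width of 349 bp and median percentiles of 38.7 in hypoxia replicate 1 and 31.2 in hypoxia replicate 2. The first by rank lay on chromosome 17 (64271709 to 64272063, 355 bp), at percentiles 91.5 and 92.2 in hypoxia replicates 1 and 2. The next lay on chromosome 12 (125412676 to 125413221, 546 bp), at percentiles 88.3 and 86.0, and the third on chromosome 19 (55591396 to 55591776, 381 bp), at 79.8 and 84.2. A further region on chromosome 12 (57824771 to 57825109) reached percentiles 78.7 and 86.4, and one on chromosome 15 (95790356 to 95790630) reached 82.8 and 79.7. Chromosome 5 held a pair of the 10 top regions (118610043 to 118610376 and 142060485 to 142060772). The others lay on chromosome 1 (222886384 to 222886842), chromosome 4 (177191862 to 177192180) and chromosome 3 (194314135 to 194314436), the last at percentile 73.8 in hypoxia replicate 1 and 94.2 in hypoxia replicate 2. Each of the 10 was a single peak in each hypoxia library, 275 to 546 bp wide.

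**Figure D3:**
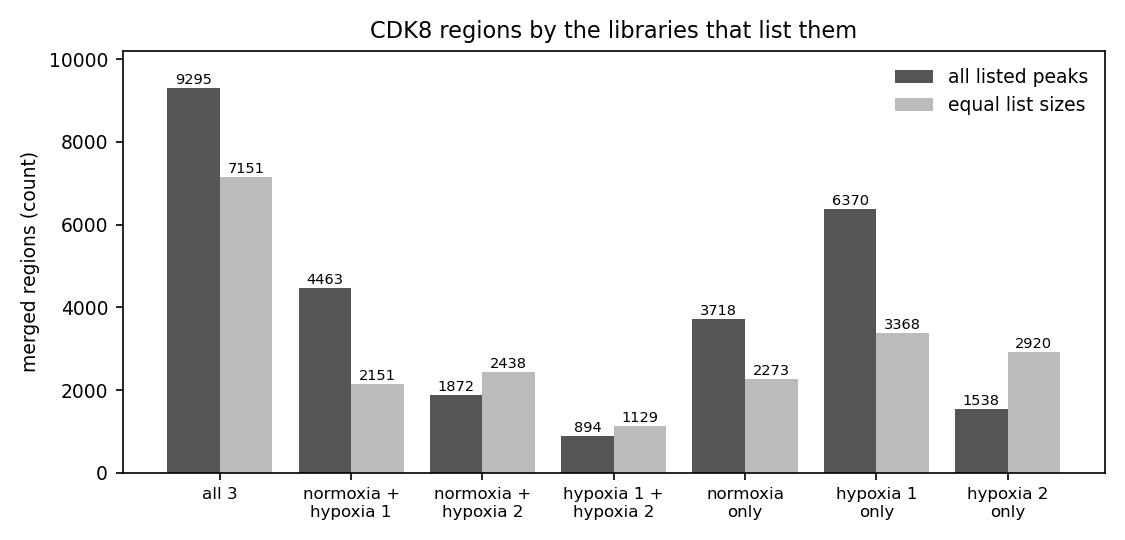
Number of joined regions by the libraries that list them, for all listed peaks (dark bars) and for equal list sizes of 14256 peaks (light bars). Regions in both hypoxia libraries and not in normoxia number 894 and 1129, fewer than in any other pattern.

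Regions lost under hypoxia were sought as those in normoxia alone. There were 3718 (13.2%, 12.8 to 13.6), which lies between the 6370 of hypoxia replicate 1 alone and the 1538 of hypoxia replicate 2 alone. With equal list sizes the counts were 2273 for normoxia, 3368 for hypoxia replicate 1 and 2920 for hypoxia replicate 2, so that normoxia had the fewest regions of its own. The normoxia count rose to 8407 without hypoxia replicate 1 and to 5700 without hypoxia replicate 2. The median percentile of the 3718 regions in the normoxia list was 23.0. The first by rank lay on chromosome 6 (18749695 to 18749992, 298 bp), at percentile 91.5. It was followed by regions on chromosome 18 (46502128 to 46502689, 562 bp) at 88.3, chromosome 19 (3366614 to 3366922) at 86.6 and chromosome 9 (139137320 to 139137709) at 86.0. The remaining 6 of the 10 lay on chromosome 14 (77030921 to 77031307), chromosome 19 (4402551 to 4402893), chromosome 2 (48132640 to 48132950), chromosome 15 (90545152 to 90545553), chromosome 10 (13389584 to 13390066) and chromosome 1 (41445043 to 41445939), at percentiles of 84.6 to 85.9.

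Among chromosomes 1 to 22 and X, CDK8 peaks were densest on chromosome 19 in all 3 libraries, with 20.9 peaks per Mb in normoxia, 21.7 in hypoxia replicate 1 and 16.1 in hypoxia replicate 2. Chromosome 17 followed, with 16.7, 17.8 and 12.1 peaks per Mb, and chromosome 22, with 15.2, 16.5 and 10.5. Chromosome X was the sparsest of these chromosomes, with 2.26, 2.55 and 1.66 peaks per Mb. Chromosomes 19, 17 and 22 are known as gene-dense chromosomes. On chromosome 21, hypoxia replicate 1 had 8.74 peaks per Mb, against 5.15 in normoxia and 3.92 in hypoxia replicate 2. Of its 334 peaks there, 145 lay in 3 windows of 1 Mb from 9 to 12 Mb. These windows were chosen after the data were seen, because hypoxia replicate 1 alone listed most regions in them. Leaving them out therefore lowers the density of hypoxia replicate 1 by construction. Outside them the densities were 5.24, 5.38 and 4.05 peaks per Mb in hypoxia replicate 1, normoxia and hypoxia replicate 2. HCT116 carries gained chromosome arms, which add reads to precipitated and input DNA alike.

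**Figure D4:**
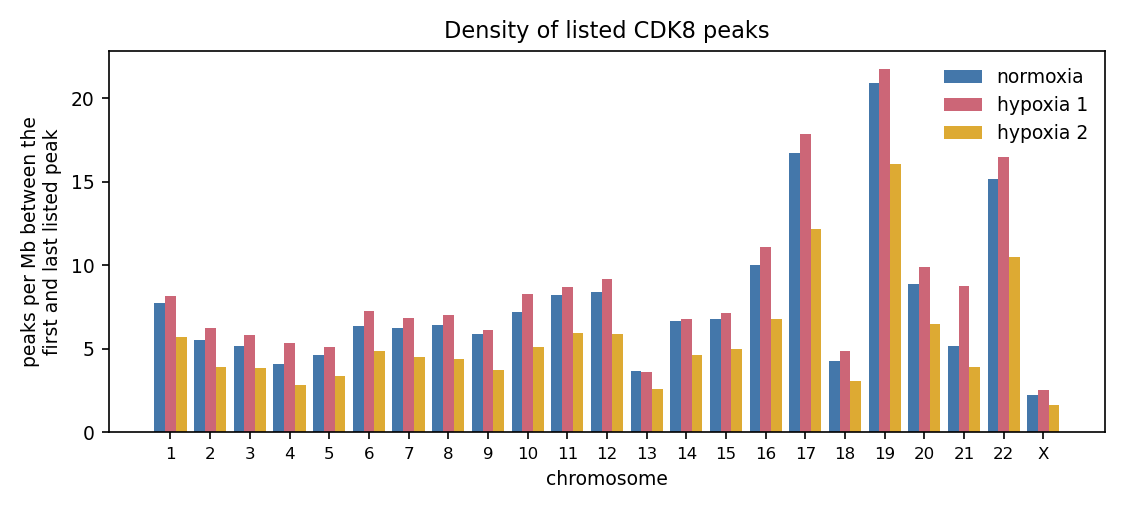
CDK8 peaks per Mb, between the first and last listed peak of each chromosome, in normoxia (blue), hypoxia replicate 1 (red) and hypoxia replicate 2 (yellow). Chromosome 19 has the highest bars in each library, at 20.9, 21.7 and 16.1 peaks per Mb.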

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

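The windows, and the use of each value below as a test of an explanation, were chosen after the results, and an annotation of chromosome bands, had been seen; equal list sizes as a setting were planned.

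Hypoxia replicate 1 listed 122 peaks on chromosome Y (0.555% of its peaks, 0.465 to 0.662), where both other libraries listed 0. It also held 636 regions of its own in 21 windows of 1 Mb on 13 other chromosomes, windows in which it alone listed at least 10 regions and at least 80% of all regions. No window met this rule for normoxia or for hypoxia replicate 2. Off chromosome Y, the fullest window lay on chromosome 21 from 10 to 11 Mb, with 95 peaks in hypoxia replicate 1 and 0 in the other libraries. Next off chromosome Y was chromosome 4 from 49 to 50 Mb, with 72 against 0 and 0. Chromosome 10 from 42 to 43 Mb followed, with 52 against 1 in normoxia and 3 in hypoxia replicate 2. Of the 20 best-ranked regions of hypoxia replicate 1 alone, 10 lay in these windows or on chromosome Y. Of all 6370 regions of hypoxia replicate 1 alone, 5612 lay outside the windows and chromosome Y. Whether some of those outside are of the same kind as those inside was not tested. The chromosome Y peaks were concentrated too, with 59 from 13 to 14 Mb, 22 from 58 to 59 Mb, 20 from 10 to 11 Mb and 12 from 59 to 60 Mb. In the 21 windows normoxia listed 18 peaks and hypoxia replicate 2 listed 27. In the windows, the near lack of peaks from the other libraries follows from the rule that chose them.

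A response to hypoxia that both hypoxia libraries could show would give such peaks in each. In 25 windows chosen by the same rule from normoxia and hypoxia replicate 1 alone, hypoxia replicate 2 had 0.189% (0.130 to 0.275) of its peaks. Hypoxia replicate 1 had 3.51% (3.27 to 3.76) there, a share raised by the choice, since its own peaks picked the windows. Normoxia had 0.237% (0.178 to 0.315) in 28 windows chosen without it. The low share in hypoxia replicate 2 does not exclude a response, since preparation, calling or depth may have kept such peaks out of its list. List length alone did not account for the chromosome Y peaks: with equal list sizes, hypoxia replicate 1 still held 95 there and the others 0. In the windows and on chromosome Y together it held 506, against 16 in normoxia and 27 in hypoxia replicate 2. The windows were chosen for this contrast, so that count is no test of list length. Different library preparation or peak calling of hypoxia replicate 1 remains a candidate explanation, since its shortest listed peak was 181 bp, against 226 bp in normoxia and 225 bp in hypoxia replicate 2, a value that fragment length or caller settings can set. Whether reads, control or caller settings differed is open.

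The 2 hypoxia libraries shared fewer peaks with each other than either shared with normoxia. Unequal list lengths did not account for this, since with equal list sizes the index of the hypoxia libraries was 60.4% (59.9 to 61.0), below the 67.4% and 69.8% of the pairs with normoxia. A change of CDK8 under hypoxia larger than the differences between libraries could make ranks more alike between the hypoxia libraries than with normoxia. Across the 9295 regions in all 3 lists the order was the reverse. Spearman's rho was 0.475 (0.458 to 0.492) for the hypoxia libraries. It was 0.627 (0.614 to 0.641) for normoxia with hypoxia replicate 1 and 0.615 (0.601 to 0.630) with hypoxia replicate 2. Regions gained or lost under hypoxia are left out of these values. A more complete normoxia library could also raise both values with normoxia. The ranks therefore cannot decide whether such a change took place. A smaller change was not tested. A normoxia library more complete than the others may account for the pattern: with equal list sizes it listed 86.4% of the regions shared by the hypoxia libraries, but that is the same overlap counted another way, and without read depths this explanation cannot be told apart from others.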

How the results depend on the processing

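Leaving out chromosome Y and the windows of hypoxia replicate 1 was chosen after the data were seen; the other alternatives were planned. The index of the 2 hypoxia libraries was the lowest of the 3 pairs in each alternative run for it, which leaves out joining within 500 bp. Regions in both hypoxia libraries and not in normoxia were the smallest of the 7 patterns in each alternative with all 3 libraries run for them, which leaves out both other overlap rules. With the better-scoring 50% of each list, by construction, 9931, 10996 and 7128 peaks were left in normoxia, hypoxia replicate 1 and hypoxia replicate 2, and 565 regions in both hypoxia libraries and not in normoxia and 2012 in normoxia alone. The index of the hypoxia libraries was then 54.5%, that of normoxia and hypoxia replicate 1 was 65.3%, and that of normoxia and hypoxia replicate 2 was 64.5%. With equal list sizes these 3 indices were 60.4%, 67.4% and 69.8%, and 2273 regions were in normoxia alone. With an overlap of 50% of both peaks, a stricter rule, they were 45.9%, 54.1% and 55.6%, and top-quintile shares in both other lists were 66.4% for normoxia, 64.9% for hypoxia replicate 1 and 72.4% for hypoxia replicate 2. With peak centres within 500 bp the first 2 indices were 60.0% and 69.5%, and the top-quintile shares were 86.6%, 77.9% and 89.7%. Without chromosome Y and the windows of hypoxia replicate 1, the first 2 indices were 60.1% and 70.1%. Beyond what fewer peaks or a stricter or looser rule bring by construction, the cause was not tested. Without either hypoxia replicate, normoxia lacked 2478 to 7352 regions of the other and held 5700 to 8407 regions that the other lacked, since a single library then decides. Of 60 alternative values, 28 stayed within their interval or within 1.5 times the main count and 32 did not. No paired analysis was possible because only 1 normoxia library exists and its label carries no replicate number. The comparisons of genomic class, genes, fixed gene lists and motifs were not run under any setting. Depth is unknown, so a peak missing from a list may lie below its threshold.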

Other observations

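All tests in this part were chosen after the data were seen. Part of the regions found in all 3 libraries lay in clusters. Of the 9295 regions, 3186 (34.3%, 33.3 to 35.2) were within 10 kb of another, in 1251 clusters, where 100 random placements gave a mean of 8.00% and at most 9.14%. There were 73 clusters of 5 or more regions, against at most 1 in the random placements, which ignore that peaks favour some parts of a chromosome. The placements also scatter the pieces of any broad enrichment called as several peaks, which here count as separate regions. Within 1 kb of another peak of the same list lay 29.9% of peaks in normoxia, 30.6% in hypoxia replicate 1 and 24.2% in hypoxia replicate 2. How much such splitting adds to the clusters was not tested. The cluster with the most regions spanned 39.7 kb on chromosome 7 (130563671 to 130603404) and held 14 regions, with 23 peaks in normoxia, 30 in hypoxia replicate 1 and 23 in hypoxia replicate 2. Peaks covered 24.6 kb of it in normoxia, 21.2 kb in hypoxia replicate 1 and 13.7 kb in hypoxia replicate 2. Next came clusters of 10 regions on chromosome 10 (114276395 to 114309148) and chromosome 11 (118779780 to 118801212), and one of 9 regions on chromosome 19 (12885733 to 12917677). Chromosome 19 held 2 further clusters among the 10 with the most regions (1239916 to 1276326 and 13944013 to 13973338), each with 8 regions.

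Regions that lacked a single library were often close to a peak of that library. Of the 894 regions in both hypoxia libraries and not in normoxia, 396 (44.3%, 41.1 to 47.6) lay within 10 kb of a normoxia peak, where random placements gave 11.0%. The share was 41.2% (39.7 to 42.6) for the regions that hypoxia replicate 2 lacked and 40.3% (38.1 to 42.6) for those that hypoxia replicate 1 lacked, against 8.69% and 12.1% in random placements. These shares lay near each other, but the shares in random placements differed between the lists. The placements also ignore that peaks favour some parts of a chromosome. Whether the regions that normoxia lacked differed in closeness from those that either hypoxia library lacked was not tested.

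The mitochondrial genome held 3 listed peaks in normoxia, 2 in hypoxia replicate 1 and 5 in hypoxia replicate 2.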
